A study of Mus musculus with 9 samples.

How the data were processed

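RNA was measured in 9 libraries of mouse leukaemic cells, haematopoietic progenitors of the C57BL/6 strain that carry the leukaemia fusion gene MLL-AF9 and had become resistant to the BET bromodomain inhibitor I-BET. Per the labels, these cells had been grown with 1000 nM I-BET and 10 ng/ml interleukin-3, were taken out of I-BET, transduced with a guide RNA for 24 h and then selected with 5 ug/ml puromycin for 72 h. A guide against the ROSA26 locus, a common control target, gave the first group of 3 libraries, and the guides named e11_1 and e12_2, both against HBO1, gave 3 libraries each. The labels do not say where in the gene the HBO1 guides cut. Libraries were made with a QuantSeq kit, which sequences the 3′ ends of polyadenylated RNA, so gene length has little part in the values.

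The authors deposited 1 table of the whole series, in which each value is a signal per gene in CPM, that is, the reads of a gene scaled so that all reads the counter saw make 1000000. Per the submitters' processing notes, bcl2fastq 2, HISAT2, HTSeq and edgeR were used with the mouse genome GRCm38 (mm10). The other versions, the annotation release and the strand setting of the counter are not given in the sources used here. The table has 44105 rows with 43633 distinct identifiers, because 267 identifiers stand on more than 1 row, and the 472 repeated rows were dropped. Over distinct identifiers each library summed to 1000000, whereas the plain sums with repeats exceeded it. 5 of the identifiers are HTSeq's own classes of reads without a gene, which held 52.6% to 57.8% of reads. They were left out of every test but remain in the denominator of the CPM as deposited. Of the 43628 gene identifiers, 19750 had a read in any library.

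Every deposited value was a whole multiple of what 1 read is worth in its library. Dividing by that step gave whole reads for 100% of values within a tolerance of 0.001 read, so depth could be recovered: 9064938 to 12144755 reads per library in all, and 4071950 to 5539052 in genes. At that depth 1 read corresponded to 0.0823 to 0.110 CPM. Counts of the same group differed by more than sampling noise in every pair of libraries, with a chi-square of 5.51 to 9.50 per degree of freedom, so no library appeared to be deposited more than once.

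Genes with at least 1 CPM in at least 3 libraries were kept, which left 9953. The table gave a symbol for 9848 of them, 88 more were named by identifier from GENCODE M21, and 17 had none. Tests ran on log2(CPM + 0.5) with limma 3.58.1 in R 4.3.3, using lmFit, contrasts.fit and eBayes with a mean-variance trend. All 9 libraries entered 1 fit with 3 group means and 6 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are on the log2(CPM + 0.5) scale, which understates the change of genes with few reads. The contrasts were the mean of both HBO1 guides against ROSA26, each guide against ROSA26, and e12_2 against e11_1. No label says that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

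30 gene lists were fixed before the data were examined, and 24 with at least 3 measured members were tested with camera, limma's competitive set test, at a preset correlation of 0.01 between genes and with adjustment over the lists. The lists covered HBO1 complex subunits, other lysine acetyltransferases, the Hoxa cluster, other MLL fusion targets, stem and progenitor genes, primary granule, late neutrophil and monocyte genes, Myc and ribosome biogenesis, DNA replication, G2 and mitosis, p53 targets, apoptosis regulators, interferon response, NF-kB, Wnt targets, integrated and ER stress, heat shock, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, mitochondrially encoded mRNAs, ribosomal proteins, and markers of mast cells, eosinophils, erythroid cells, megakaryocytes, dendritic cells, B cells, and T and NK cells. List members were matched to older symbols of the table through RefSeq synonyms. Counts of list members below are of those measured, which for several lists were only a part. Measured were 12 of 32 interferon response, 11 of 24 monocyte and macrophage and 13 of 22 NF-kB and inflammatory genes. For late neutrophil genes it was 16 of 22, and for stem and progenitor genes 11 of 18.

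Genes to name were also fixed by a rule in advance. They were Kat7, the gene of HBO1, and the 12 genes with the largest rise and the 12 with the largest fall for both guides, among genes past the threshold, of the same sign with each guide, with no overlap between the groups' libraries, with a group mean of at least 5 CPM, and with a symbol other than a gene-model name. Likewise 4 genes each way were taken for each other contrast, up to 4 passing members with the largest change for each list, and the 2 members with the smallest p where none passed. Any other gene is said to have been chosen after its values were seen. Coordinates are those of GENCODE M21 on GRCm38. A gene was called uncertain where another tested gene overlaps it, because the strand setting is unknown, or where it has near-identical relatives.

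The fitting code was tested on simulated reads drawn from the real libraries' means and sizes. Among 9791 genes, 67 were changed 1.5-fold, 65 were changed 2-fold and 63 were changed 4-fold. For both guides it recovered 46.3%, 84.6% and 100% of these. For e11_1 the shares were 34.3%, 83.1% and 100%, and for e12_2 they were 31.3%, 76.9% and 98.4%. For a change in e12_2 alone, set against e11_1, they were 37.3%, 75.8% and 96.9% of 67, 66 and 65 changed genes among 9784. Simulated noise followed a trend of spread with level and held no shift shared by replicate number. Far fewer genes were changed than were called in the real libraries, so the shares may not carry over to them.

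Alternatives were a pseudocount of 0.1 or 2, no filter or a filter of 5 CPM, median centring, quantile normalization, no variance trend, array weights, a replicate block, the compared groups alone, each library left out, a threshold of 0.01, limma's treat against a 1.5-fold change, camera with an estimated correlation, fry, and the HBO1 complex list without Kat7. On the recovered reads, edgeR 4.0.16 with its quasi-likelihood test and TMM scaling, and DESeq2 1.42.0, were run. The alternatives added after the data were seen were scaling to gene reads, scaling to gene reads without Gm26924 and the mitochondrial rRNAs, and leaving out the 3 libraries numbered 1. Values were prepared and plotted with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.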

Results

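3′ mRNA libraries were compared between MLL-AF9 leukaemic cells that had become resistant to I-BET and then received either a control guide (ROSA26) or 1 of 2 guides against HBO1 (e11_1 and e12_2), with 3 libraries in each group. HBO1 is a histone acetyltransferase encoded by Kat7. The study set out to learn whether leukaemia stem cells depend on it, here in cells that no longer respond to BET inhibition. Libraries held 9064938 to 12144755 reads, of which 4071950 to 5539052 fell in genes. The gene model Gm26924 alone took 9.24% to 14.1% of the gene reads. The first principal component held 62.5% of the variance and separated the ROSA26 libraries, at -48.1 to -37.1, from all 6 HBO1-guide libraries, at 19.1 to 22.4. The second component, with 11.7%, set the 3 libraries numbered 1, at 14.3 to 20.7, apart from the other libraries, at -11.1 to -5.59.

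**Figure D1:**
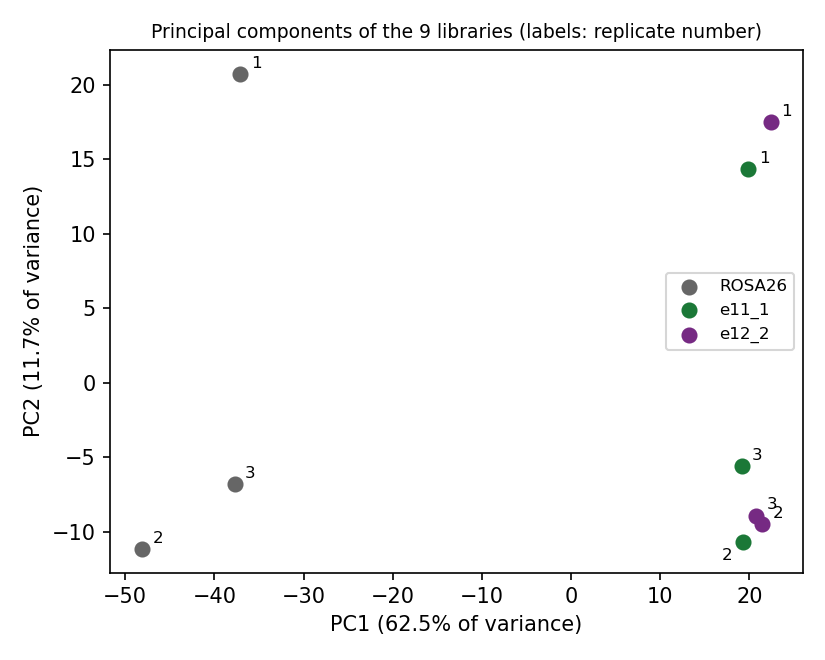
Principal components of the log2(CPM + 0.5) values of the 9 libraries, PC1 (62.5% of variance) on the horizontal and PC2 (11.7%) on the vertical axis, coloured by guide and labelled with the replicate number. ROSA26 libraries lie at -48.1 to -37.1 on PC1 and HBO1-guide libraries at 19.1 to 22.4, and the libraries numbered 1 lie at 14.3 to 20.7 on PC2.

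Kat7 itself was lower with each HBO1 guide. Kat7 (ENSMUSG00000038909, GRCm38 chromosome 11, 95274259 to 95310246, minus strand) measured 39.5 ± 2.60 CPM (SD, n = 3) with the ROSA26 guide, 21.3 ± 0.845 CPM (SD, n = 3) with e11_1 and 16.3 ± 1.66 CPM (SD, n = 3) with e12_2. The log2 fold change was -1.06 for both guides (SE 0.11, limma adjusted p = 2.0e-06), which is 2.09-fold lower. It was -0.87 with e11_1 (SE 0.12, limma adjusted p = 8.6e-05) and -1.26 with e12_2 (SE 0.12, limma adjusted p = 2.4e-06). All 6 HBO1-guide libraries lay below all 3 ROSA26 libraries, and no other split of the 9 libraries into 6 and 3 gave as large a difference (two-sided exact permutation p = 0.0119, 84 splits). With 3 libraries against 3, the exact permutation p was 0.1 for each guide, the smallest this size allows. Reads from the 3′ end count remaining transcripts and may miss a small disruption elsewhere in the gene, so the level alone does not tell how much working protein was left.

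With both HBO1 guides, S100a9 and Ngp had the largest rises on the log2 scale of the main fit. The order depends on that scale, since Stfa2l1 was at 7.55 with DESeq2. S100a9, a calcium-binding protein abundant in neutrophils (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721), went from 18.9 ± 13.0 CPM (SD, n = 3) with ROSA26 to 1391 ± 108 CPM with e11_1 and 1326 ± 226 CPM with e12_2 (SD, n = 3 each). That was a log2 fold change of 6.51 (SE 0.40, limma adjusted p = 1.1e-08), or 91.4-fold higher. Its partner S100a8 went from 51.0 ± 28.1 to 2566 ± 547 and 2403 ± 668 CPM (log2 fold change 5.77, SE 0.31). Ngp, a neutrophil granule protein (ENSMUSG00000032484, chromosome 9, 110419747 to 110423012), went from 7.03 ± 4.70 to 497 ± 72.7 and 506 ± 85.7 CPM (6.35, SE 0.35, limma adjusted p = 3.3e-09). Without ROSA26 replicate 2 the rises were smaller for S100a9 at 5.65 (50.2-fold higher), S100a8 at 5.17 and Ngp at 5.61 (48.9-fold higher).

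The stefin A protease inhibitors Stfa2l1 and Stfa2, also among the 12 largest rises, rose by log2 fold changes of 5.97 (7.55 with DESeq2) and 5.80, values that are uncertain because near-identical relatives can share reads. The chemokine Ccl6 rose from 1.10 ± 0.672 to 63.1 ± 33.8 and 73.7 ± 31.4 CPM (5.40, SE 0.33), and the antimicrobial peptide gene Camp from 1.84 ± 1.43 to 27.7 ± 8.59 and 33.5 ± 20.1 CPM (3.92, SE 0.42, or 3.19 without ROSA26 replicate 2). Ncf1, a subunit of the phagocyte NADPH oxidase, rose from 4.41 ± 0.998 to 62.4 ± 5.10 and 63.7 ± 9.46 CPM (3.71, SE 0.13, limma adjusted p = 2.0e-11), and Igsf6 rose by 4.25 (SE 0.20). Ncf1 and Igsf6 overlap the tested genes Gtf2ird2 and Mettl9, and are uncertain for that reason. Ankrd22 (3.66, or 5.30 with DESeq2), the neutrophil surface protein gene Cd177 (3.62, or 5.63 with DESeq2) and Mogat2 (3.59) completed the set.

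Among the falls, the junction protein gene Cgnl1 and the drug efflux pump gene Abcb1a led on the log2 scale of the main fit. Their lead depends on that scale, since with DESeq2 Parm1 was at -5.02 and Abcb1a at -4.59. Cgnl1 (ENSMUSG00000032232, chromosome 9, 71626509 to 71771602) went from 147 ± 20.4 to 8.37 ± 2.58 and 7.95 ± 1.10 CPM, a log2 fold change of -4.11 (SE 0.16, limma adjusted p = 4.0e-11), or 17.2-fold lower. Abcb1a (ENSMUSG00000040584, chromosome 5, 8660077 to 8748575) went from 24.0 ± 8.19 to 0.934 ± 0.119 and 1.09 ± 0.386 CPM, a log2 fold change of -3.98 (SE 0.23, limma adjusted p = 4.9e-09), or 15.7-fold lower (24.1-fold with DESeq2). It is uncertain in part because Abcb1b is a close paralog. Hpgd, which inactivates prostaglandins, went from 370 ± 54.3 to 46.9 ± 5.59 and 44.2 ± 5.74 CPM (-3.01, SE 0.11, limma adjusted p = 4.0e-11). The monocyte chemokine receptor gene Ccr2 went from 34.4 ± 13.2 to 3.0 ± 0.938 and 3.57 ± 0.429 CPM (-3.17, SE 0.21). The other falls were those of the secreted Wnt antagonist gene Frzb (-3.58), Pde11a (-3.48), Parm1 (-3.48), Ccdc80 (-3.39), Lypd6 (-3.13), the kynureninase gene Kynu (-2.98), Stc1 (-2.90) and Slitrk6 (-2.84). With DESeq2, Kynu was at -4.29, Stc1 at -4.28 and Slitrk6 at -3.50.

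Over all genes, limma called 3623 of 9953 for both guides against ROSA26, 1897 higher and 1726 lower. Of these, 435 were more than 2-fold higher and 339 more than 2-fold lower. More were lower than higher with CPM over gene reads (1683 higher, 2054 lower), after quantile normalization (1805 and 2011), without Gm26924 and mitochondrial rRNAs (1796 and 1923) and with no filter (1759 and 1830). On recovered reads, edgeR called 3718, of which 3594 were also called by limma, and DESeq2 called 3441. The 24 genes with the largest changes kept their calls under each alternative that could test them. Parm1, Kynu, Slitrk6 and Stc1 were below the filter, and so had no test, without any 1 of the ROSA26 libraries and without the 3 libraries numbered 1, Stc1 also with a filter of 5 CPM. Of all 107 genes named for both guides other than Kat7, 90 kept the call wherever tested, 15 lost it when some single library was left out, and 12 had no test under at least 1 alternative.

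**Figure D2:**
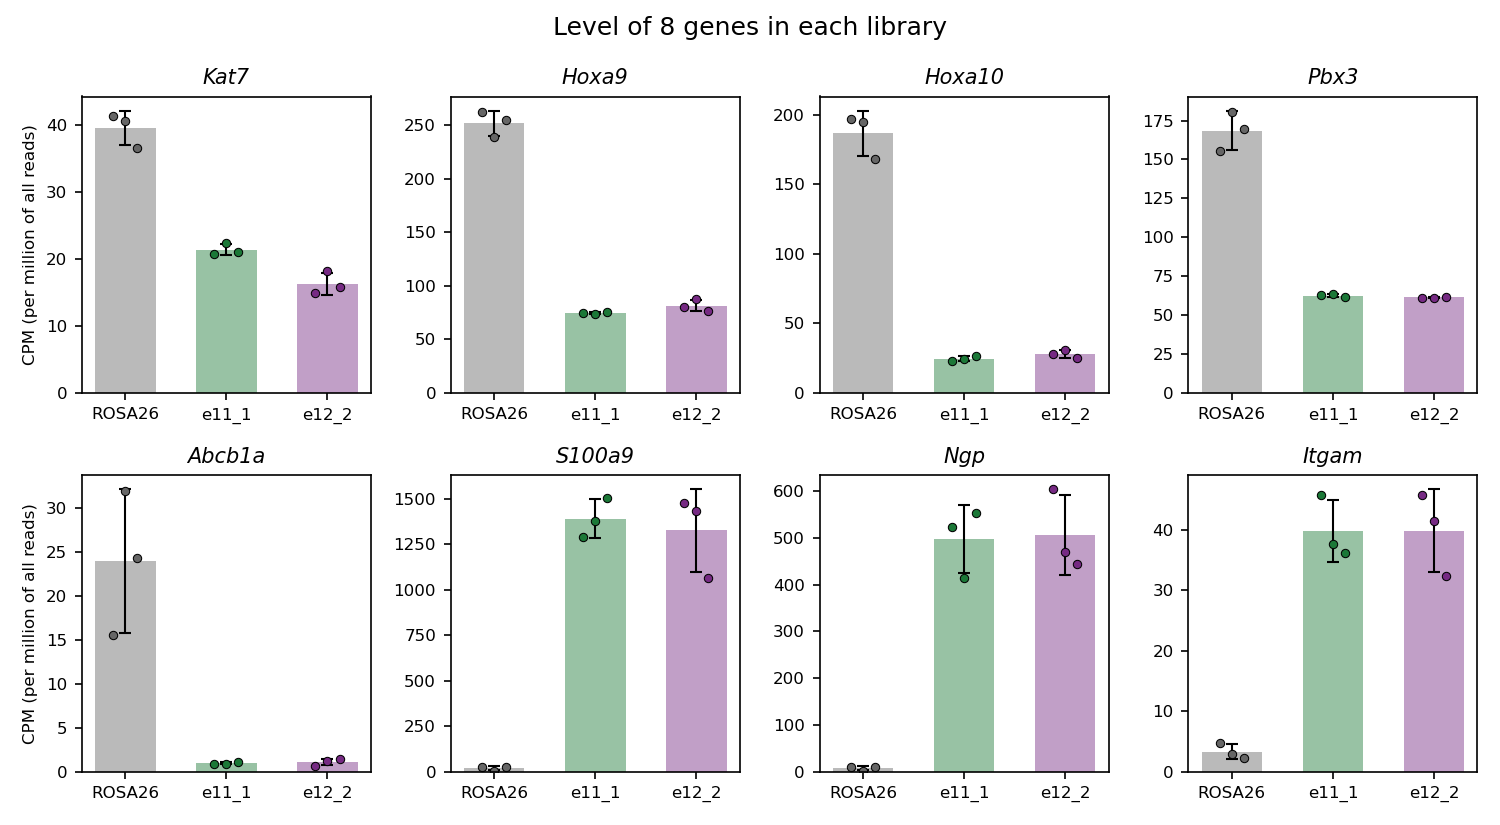
CPM of 8 genes in each library (points) with the group mean (bars) and SD (error bars, n = 3), on axes that start at 0. Kat7 falls from 39.5 to 21.3 and 16.3 CPM, Hoxa9, Hoxa10, Pbx3 and Abcb1a fall as well, and S100a9, Ngp and Itgam rise with both HBO1 guides.

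All 5 measured Hoxa genes, transcription factors that MLL fusions switch on, fell with both HBO1 guides. Hoxa10 (chromosome 6, 52231197 to 52240854) went from 187 ± 16.2 to 24.6 ± 1.75 and 27.8 ± 2.70 CPM (SD, n = 3 each), a log2 fold change of -2.81 (SE 0.10, limma adjusted p = 1.9e-11). Hoxa9 (chromosome 6, 52223100 to 52231089) went from 252 ± 11.9 to 74.6 ± 1.10 and 81.4 ± 5.30 CPM (-1.68, SE 0.08, limma adjusted p = 9.3e-10). Hoxa5 (-1.70) and Hoxa11 (-1.33) fell too, though each overlaps a tested transcript on the other strand and is uncertain. With 0 of 5 higher and 5 lower, and the same numbers when adjusted over the list alone, the median was -1.68 and the camera adjusted p = 4.7e-06, against an adjusted p = 0.0691 with an estimated correlation. Of 17 other MLL fusion targets, 9 fell, 2 rose and 6 did not pass, and the counts were the same adjusted over the list alone. Mef2c (-2.00), Eya1 (-1.82) and the Hoxa cofactor gene Pbx3 (169 ± 12.8 to 62.4 ± 0.980 and 61.3 ± 0.454 CPM, -1.44) fell, whereas Id2, an inhibitor of DNA-binding factors, rose by 1.51. The median of that list was -0.82 with a camera adjusted p = 0.000152 and an adjusted p = 0.261 with an estimated correlation, and it was -0.51 without ROSA26 replicate 2 (camera adjusted p = 0.000817).

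Of 11 stem and progenitor genes, 6 fell, 1 rose and 4 did not pass, with the same counts adjusted over the list alone. Angpt1, a ligand of the Tie receptor, fell from 107 ± 18.1 to 20.5 ± 4.65 and 20.9 ± 5.97 CPM (-2.36, SE 0.17), and the progenitor surface marker gene Cd34 (-1.59) and Ikzf2 (-1.50) fell as well. Prom1, which encodes the stem cell marker prominin, went the other way and rose by 2.26. The median was -0.42 with a camera adjusted p = 0.0183, and the adjusted p = 0.261 with an estimated correlation.

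Late neutrophil genes gave the largest shift of the 24 lists. Of 16 measured, 14 rose, 0 fell and 2 did not pass. Adjusted over the list alone 15 rose. The median was 2.04, with a camera adjusted p = 6.8e-13 and an adjusted p = 0.189 with an estimated correlation. ROSA26 replicate 2 stood apart from its group here: S100a8 measured 18.7 CPM in it against 70.3 and 64.1 CPM in ROSA26 replicates 1 and 3, and Ngp measured 1.68 against 10.5 and 8.93 CPM. Of 11 primary granule genes, 7 rose, 1 fell and 3 did not pass, as they did adjusted over the list alone. The myeloperoxidase gene Mpo (2.41, SE 0.54) and the protease genes Elane (2.07) and Prtn3 (1.40) rose with Plac8 (1.33). Prtn3 overlaps BC005764 and is uncertain. The median was 0.95, with a camera adjusted p = 0.00559 and an adjusted p = 0.389 with an estimated correlation.

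Monocyte and macrophage genes moved in both directions. Of 11, 8 rose, 2 fell and 1 did not pass, and adjusted over the list alone 9 rose and 2 fell. The integrin gene Itgam, which encodes CD11b, rose from 3.30 ± 1.30 to 39.8 ± 5.16 and 39.8 ± 6.88 CPM (3.45, SE 0.18, limma adjusted p = 1.7e-09), and the signalling adaptor gene Tyrobp (3.05) and Lgals3 (1.98) rose. Ccr2 fell. The median was 0.92, with a camera adjusted p = 0.000195 and an adjusted p = 0.261 with an estimated correlation. Of 13 NF-kB and inflammatory genes, 9 rose, 0 fell and 4 did not pass, with the same counts adjusted over the list alone. Besides Ccl6, the rises included Il1rn (7.98 ± 0.789 to 59.9 ± 3.47 and 62.6 ± 4.06 CPM, 2.87), which blocks the interleukin-1 receptor, and Nfkbia (1.21), which holds NF-kB in the cytoplasm, beside the NF-kB subunit gene Rel (1.41). The median was 0.94, with a camera adjusted p = 3.0e-05 and an adjusted p = 0.0691 with an estimated correlation.

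Genes of ribosome biogenesis fell while several of division rose. Of 22 Myc and ribosome biogenesis genes, 15 fell, 0 rose and 7 did not pass, and adjusted over the list alone 20 fell and 1 rose. Cad (-1.12), Srm (-0.80), Polr1b (-0.79) and Npm1 (2376 ± 157 to 1434 ± 46.4 and 1368 ± 52.3 CPM, -0.76) were the largest. The median was -0.52, with a camera adjusted p = 2.3e-07 and an adjusted p = 0.261 with an estimated correlation. Of 24 G2 and mitosis genes, 13 rose, 0 fell and 11 did not pass, against 16 that rose adjusted over the list alone. Cenpa (0.85) and the proliferation marker gene Mki67 (109 ± 6.80 to 169 ± 3.26 and 168 ± 9.18 CPM, 0.62) rose, as did Nusap1 (0.78) and Ccna2 (0.71), which overlap Oip5 and Exosc9 and are uncertain. The median was 0.34, with a camera adjusted p = 2.4e-05 and an adjusted p = 0.261 with an estimated correlation. Of 30 DNA replication genes, 9 rose, 3 fell and 18 did not pass, also adjusted over the list alone, among them the helicase genes Mcm4 (1.22) and Mcm6 (0.68), the ribonucleotide reductase gene Rrm2 (0.91) and Slbp (0.87), which rose. That list was not called (camera adjusted p = 0.058, median 0.16). Without ROSA26 replicate 2, Cenpa was at 0.45 and Mcm6 at 0.43.

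Neither p53 targets nor apoptosis regulators were called as lists. Of 21 p53 targets, 3 rose, 2 fell and 16 did not pass, and adjusted over the list alone 2 rose and 2 fell (median -0.11, from -0.24 without e12_2 replicate 1 to 0.015 without ROSA26 replicate 1, camera adjusted p = 0.394). Zmat3 (-1.09) and Ei24 (-0.47) fell. Pmaip1 (0.73) and Mdm2 (0.30) rose, but Pmaip1 was at 0.38 without ROSA26 replicate 2 (limma adjusted p = 0.121), and Mdm2 had limma adjusted p = 0.0551 without ROSA26 replicate 3. Of 18 apoptosis regulators, 7 rose, 1 fell and 10 did not pass, also adjusted over the list alone (median 0.31, or 0.18 without ROSA26 replicate 2, camera adjusted p = 0.056). Casp6 (1.13), Bcl2l11 (1.11), which encodes the pro-death protein Bim, and the apoptosome gene Apaf1 (1.04) rose and the survival gene Bcl2 fell from 24.0 ± 2.92 to 11.4 ± 1.94 and 12.5 ± 2.45 CPM (-0.99). The survival genes Cflar (0.71) and Mcl1 (0.51), chosen after their values were seen, rose as well.

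Some antiviral and protein-folding genes fell. Of 12 interferon response genes measured, from 32 in the list, 5 fell, 0 rose and 7 did not pass, also adjusted over the list alone. Gbp3 (-1.75), the RNA sensor gene Ifih1 (-1.35) and Rsad2 (-1.21) led the falls. The median was -0.36, with a camera adjusted p = 0.0315 and an adjusted p = 0.389 with an estimated correlation, and it was -0.17 without ROSA26 replicate 1. Of 22 integrated and ER stress genes, 8 fell, 2 rose and 12 did not pass, against 9 and 2 adjusted over the list alone. Nupr1 (-1.15), the serine synthesis gene Psat1 (-0.66) and Trib3 (-0.53) fell, and Xbp1, a transcription factor of the unfolded protein response, rose by 0.97. The median was -0.26, or -0.17 without ROSA26 replicate 1, with a camera adjusted p = 0.0496 and an adjusted p = 0.389 with an estimated correlation. Of 9 heat shock genes, 5 fell, 1 rose and 3 did not pass, against 6 and 1 adjusted over the list alone. The chaperone genes Hspd1 (1268 ± 128 to 645 ± 42.0 and 659 ± 29.0 CPM, -0.96), Hsph1 (-0.65), Hspa8 (-0.56) and Hsp90ab1 (-0.56) fell, the last without a call after quantile normalization (limma adjusted p = 0.191). Hspd1 overlaps Hspe1 and is uncertain, and the list was not called (camera adjusted p = 0.058, median -0.43).

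Metabolic genes were compared in 5 lists. Of 40 oxidative phosphorylation genes, 12 rose, 3 fell and 25 did not pass, also adjusted over the list alone. Ndufa1 (1.08), Ndufb3 (1.03, or 0.67 without ROSA26 replicate 2), Sdhc (0.98) and Atp5h (0.71) rose. The median was 0.13, or 0.19 without ROSA26 replicate 3, with a camera adjusted p = 0.0496 and an adjusted p = 0.581 with an estimated correlation. Of 23 glycolysis and hypoxia genes, 6 rose, 1 fell and 16 did not pass, also adjusted over the list alone (median 0.04, from -0.083 without ROSA26 replicate 2 to 0.20 without ROSA26 replicate 1, camera adjusted p = 0.264), and the glucose transporter gene Slc2a3 rose from 5.89 ± 1.19 to 26.6 ± 7.70 and 24.8 ± 8.42 CPM (2.01). Mxi1 (0.93), an antagonist of Myc, and Tpi1 (0.82, or 0.50 without ROSA26 replicate 2), which overlaps Spsb2 and is uncertain, rose with it. Of 22 cholesterol synthesis genes, 4 rose, 0 fell and 18 did not pass, against 1 that rose adjusted over the list alone (median 0.31, or 0.13 without ROSA26 replicate 2, camera adjusted p = 0.0638), the largest rise being that of Fdps (0.69). Of 10 mitochondrially encoded mRNAs, 1 fell, 0 rose and 9 did not pass, also adjusted over the list alone (median -0.06, from -0.26 without ROSA26 replicate 1 to 0.011 without e11_1 replicate 1 and 0.068 without ROSA26 replicate 3, camera adjusted p = 0.378). The 1 was mt-Nd2 (-0.51), which had a limma adjusted p = 0.0685 without ROSA26 replicate 2. Of 61 ribosomal protein genes, 12 fell, 5 rose and 44 did not pass, against 9 and 5 adjusted over the list alone (median -0.13, but -0.060 without ROSA26 replicate 1 and -0.083 without e11_1 replicate 2, camera adjusted p = 0.058). Rpl7 fell by 0.43, without a call when the 3 libraries numbered 1 were left out (limma adjusted p = 0.0610), and Rps2, which overlaps Snhg9 and is uncertain, rose by 0.86, or by 0.48 without ROSA26 replicate 2.

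Among HBO1's own partners, 3 rose. Of 10 HBO1 complex subunits, 1 fell, Kat7, and 6 did not pass, also adjusted over the list alone (median -0.06, from -0.13 without e12_2 replicate 2 to 0.0049 without e12_2 replicate 1, camera adjusted p = 0.942). The scaffold gene Brpf1 rose from 18.7 ± 0.758 to 30.2 ± 1.70 and 33.5 ± 1.76 CPM (0.75, SE 0.10, limma adjusted p = 3.3e-05). Its relatives Brpf3 (0.67) and Brd1 (0.27) rose, but without ROSA26 replicate 2 their limma adjusted p = 0.0862 and 0.138, and 6 and 5 of the 9 libraries, when left out, ended the call. Of 10 other lysine acetyltransferases, 3 rose, 0 fell and 7 did not pass, also adjusted over the list alone (median 0.12, from 0.060 without e12_2 replicate 2 to 0.21 without e12_2 replicate 1, camera adjusted p = 0.301). They were Naa40 (0.78, or 0.52 without ROSA26 replicate 2), Hat1 (0.48) and Kat6b (0.41). Naa40 stood in the fixed list, but its enzyme acetylates the N-terminal end of histones and not a lysine. Hat1 and Kat6b had limma adjusted p = 0.126 and 0.0758 without ROSA26 replicate 2, and Kat6b had limma adjusted p = 0.0543 without ROSA26 replicate 3.

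Markers of other blood lineages were scarce. Of 4 measured mast cell and basophil markers, 2 fell, 0 rose and 2 did not pass, also adjusted over the list alone (median -0.42, but 0.094 without ROSA26 replicate 1 and 0.11 without ROSA26 replicate 2, camera adjusted p = 0.132), and these were Cpa3 (3.38 ± 0.424 to 0.427 ± 0.306 and 0.425 ± 0.0378 CPM, -2.09) and Mcpt8 (-0.88). Of 4 T and NK cell markers, 2 fell, Bcl11b (-0.85) and Lck (-0.71), 1 rose, Lat (0.46), and 1 did not pass, also adjusted over the list alone (median -0.52, camera adjusted p = 0.307). Lat had limma adjusted p = 0.143 without ROSA26 replicate 2 and limma adjusted p = 0.0517 without e11_1 replicate 2. Lists with fewer than 3 measured members were not tested. Of 13 dendritic cell markers 2 were measured, and Ciita, which overlaps Dexi and is uncertain, fell by 1.05. Of 16 Wnt targets 2 were measured, Lrp6 (-0.27, limma adjusted p = 0.215) and Znrf3 (-0.24, limma adjusted p = 0.453). Of 13 erythroid markers Tfr2 was measured (-0.27, limma adjusted p = 0.362), and of 11 megakaryocyte markers Itga2b (-0.49, limma adjusted p = 0.110), which passed without e11_1 replicate 2 (limma adjusted p = 0.0269). None of 9 eosinophil and 12 B cell markers reached the level for testing.

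In all, camera called 12 of 24 lists at the preset correlation and 0 with an estimated correlation. In a fit with 2 groups the real split called 10 lists, and 21 of the 84 ways to split the 9 libraries into 6 and 3, the real one included, called at least 10. For 10 lists, leaving out 1 library changed the side of the threshold. The interferon list was lost without ROSA26 replicate 1 (camera adjusted p = 0.104) or 2 (0.0703), and the stress list without ROSA26 replicate 1 (0.0787), e11_1 replicate 2 (0.0534) or e12_2 replicate 1 (0.0649). The oxidative phosphorylation list was lost without ROSA26 replicate 2 (0.155), e11_1 replicate 3 (0.0580) or e12_2 replicate 1 (0.0677), and also with CPM over gene reads (0.0748) and without Gm26924 and mitochondrial rRNAs (0.0551). Without ROSA26 replicate 1 the apoptosis (0.0328), heat shock (0.0383), cholesterol (0.0118), glycolysis (0.0383) and mitochondrial mRNA (0.0147) lists passed. Ribosomal proteins passed without ROSA26 replicate 2 (0.0275) or 3 (0.0152) or e11_1 replicate 3 (0.0167), and DNA replication without e11_1 replicate 1 (0.0471). With other scalings ribosomal proteins passed after quantile normalization (0.0181), with CPM over gene reads (0.0235) and without Gm26924 and mitochondrial rRNAs (0.0212), and the apoptosis and heat shock lists passed in the last of these (0.0496 each). The interferon list was also lost with no filter (0.0689), with a filter of 5 CPM (0.0732) and without the 3 libraries numbered 1 (0.0648), the stress list with a pseudocount of 2 (0.0516), with array weights (0.0604) and without the libraries numbered 1 (0.0947), and the oxidative phosphorylation list with 5 CPM (0.106), either other pseudocount (0.0510 and 0.0509), a replicate block (0.0519), array weights (0.0604) or without the libraries numbered 1 (0.0508). With no filter the DNA replication (0.00945), apoptosis (0.00927) and cholesterol (0.0282) lists passed, with 5 CPM the ribosomal one (0.0409), with array weights the apoptosis (0.0453) and with a replicate block the cholesterol list (0.00711). The heat shock list also passed without ROSA26 replicate 3 (0.0497), e11_1 replicate 2 (0.0454) or e12_2 replicate 2 (0.0486), the cholesterol list without e11_1 replicate 2 (0.00788) or e12_2 replicate 2 (0.0102), and the apoptosis list without e12_2 replicate 2 (0.0486).

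**Figure D3:**
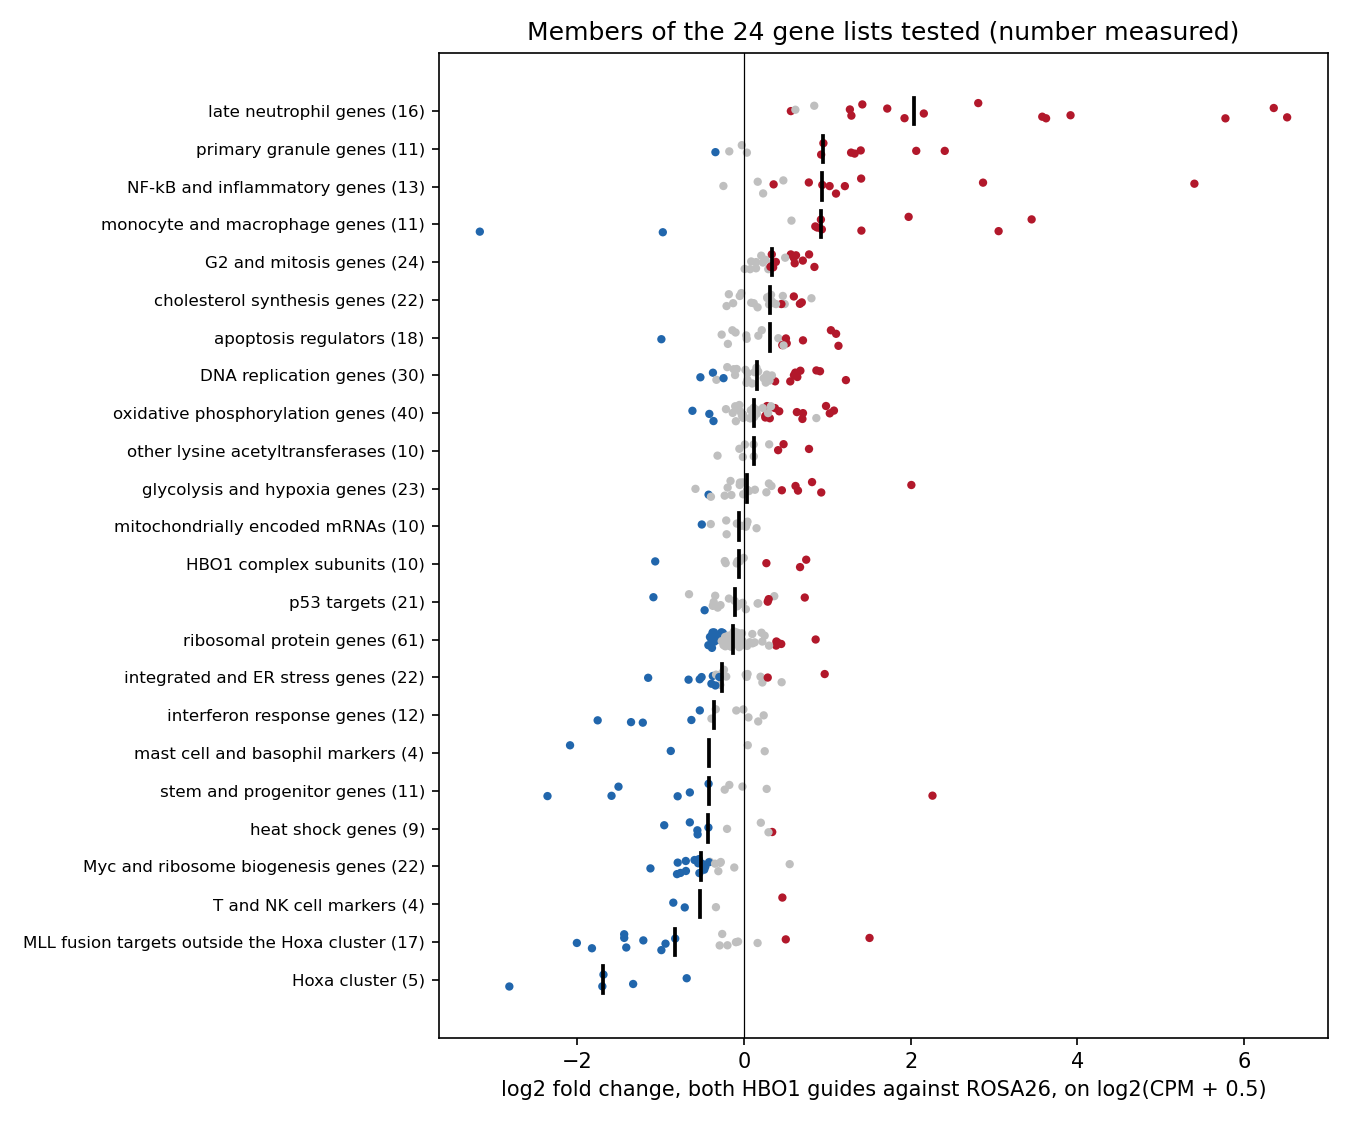
Log2 fold changes for both HBO1 guides against ROSA26 of the measured members of the 24 lists tested, with the number measured in brackets; red points were called higher, blue points lower and grey points neither, and black bars are medians. Late neutrophil genes have the highest median (2.04) and Hoxa genes the lowest (-1.68).

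With the e11_1 guide alone, S100a9 rose by a log2 fold change of 6.56 (SE 0.46, limma adjusted p = 8.2e-08), followed by Ngp (6.34), Stfa2l1 (5.89) and S100a8 (5.83). This order depends on the scale, since Stfa2l1 was at 7.48 with DESeq2. Without ROSA26 replicate 2, S100a9 was at 5.69, Ngp at 5.6 and S100a8 at 5.22. Cgnl1 (-4.09, SE 0.18, limma adjusted p = 4.0e-10), Abcb1a (-4.04), Parm1 and Ccdc80 fell most on the log2(CPM + 0.5) scale. With DESeq2 Parm1 was at -5.52 and Abcb1a at -4.68. All 5 Hoxa genes fell, 13 of 16 late neutrophil genes rose, and 15 of 22 Myc and ribosome biogenesis genes fell. limma called 2793 genes, 1396 higher and 1397 lower, edgeR 2869 (1527 higher, 1342 lower) and DESeq2 2621. With CPM over gene reads 1268 were higher and 1659 lower, and after median centring 1522 and 1379. In this contrast camera was also past the threshold for heat shock (adjusted p = 0.0476), ribosomal protein (0.0476) and stress (0.0285) genes, of which none passed with an estimated correlation (adjusted p = 0.380, 0.663 and 0.380). Oxidative phosphorylation genes did not pass with e11_1 (camera adjusted p = 0.0586).

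With the e12_2 guide alone, S100a9 rose by 6.47 (SE 0.46, limma adjusted p = 8.5e-08), followed by Ngp (6.37), Stfa2l1 (6.05) and Stfa2 (5.92). Here too the order depends on the scale, since Stfa2l1 was at 7.61 with DESeq2. Without ROSA26 replicate 2, S100a9 was at 5.61 and Ngp at 5.63. Cgnl1 (-4.13, SE 0.18, limma adjusted p = 3.2e-10), Abcb1a (-3.91), Frzb and Pde11a fell most on the log2(CPM + 0.5) scale. All 5 Hoxa genes fell here too, 14 of 16 late neutrophil genes rose, and 15 of 22 Myc and ribosome biogenesis genes fell. limma called 3106 genes, 1738 higher and 1368 lower, edgeR 3252 and DESeq2 2979. More genes were lower than higher with CPM over gene reads (1524 higher, 1676 lower), after quantile normalization (1610 and 1722) and without Gm26924 and mitochondrial rRNAs (1566 and 1652). Stress genes (camera adjusted p = 0.0816) did not pass with e12_2, nor did oxidative phosphorylation genes (0.0502), as with e11_1.

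Which genes moved with each guide was compared through their overlap. Genes such as S100a9, Itgam, Hoxa10 and Cgnl1 were among 2409 called in the same direction with each guide, 1287 higher and 1122 lower, and 0 were called in opposite directions. Independent lists of these sizes would share 436 genes, 244 higher and 192 lower. Because both contrasts use the same ROSA26 libraries, all 9 libraries were simulated without any change, with the control group again shared. The guides then shared 0.05 genes on average and at most 1 in 20 fits. Few genes pass adjustment when nothing changes, so this count does not measure the overlap that shared controls add. Noise was drawn gene by gene, so shifts common to many genes in the real ROSA26 libraries were absent. Across genes, which are not independent replicates, the fold changes of the guides correlated at 0.960, against 0.502 for unchanged groups. Their covariance was 0.372 against 0.0203, a difference of 0.352. The signs matched for 88.5% of genes, against 66.6%. With 3 control libraries no split into parts of at least 2 can be made, so part of the excess overlap may come from the shared controls.

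**Figure D4:**
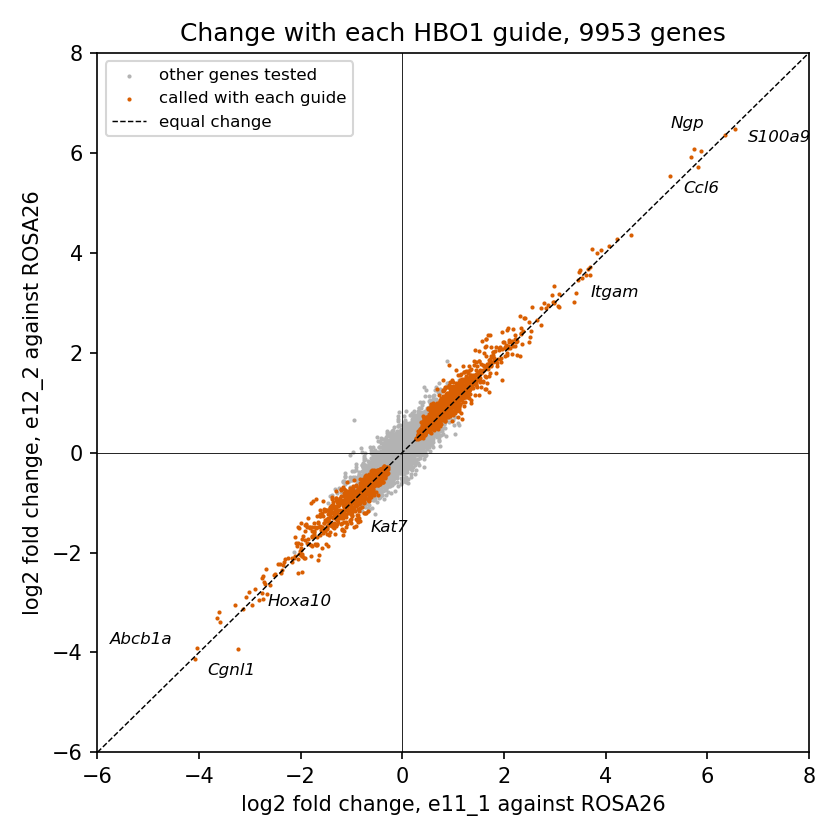
Log2 fold change of each of the 9953 tested genes with e11_1 (horizontal) and e12_2 (vertical) against ROSA26, with the 2409 genes called in the same direction with each guide in orange and the line of equal change dashed. The points follow the line, with a correlation across genes of 0.960.

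The guides themselves were then compared with each other. No gene differed between e12_2 and e11_1 by limma after adjustment (0 calls, 176 at an unadjusted p under 0.05), nor by edgeR (0 calls, 161 at an unadjusted p under 0.05) or DESeq2 (0 calls). Kat7 was lower with e12_2 by a log2 difference of -0.38 (SE 0.12), which did not pass limma after adjustment. Its exact permutation p was 0.1, the smallest that 3 libraries against 3 allow. S100a9 differed by -0.08 (SE 0.46) and Abcb1a by 0.12 (SE 0.26). The mitochondrially encoded mRNAs were higher with e12_2 as a list (median 0.27, camera adjusted p = 0.0195), with 0 of 10 members passing, 0 adjusted over the list alone, and an adjusted p = 0.967 with an estimated correlation.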

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

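Among the tests in this part, the regroupings for the counts of called genes and the list-by-list comparison were run after those results had been seen, and the regroupings for the number of called lists and for the overlap of the guides were set beforehand.

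The mitochondrially encoded mRNAs drew attention because their list differed between the HBO1 guides in a test of the difference itself, with a median log2 difference of 0.27 (e12_2 minus e11_1) and a camera adjusted p = 0.0195. With an estimated correlation the adjusted p was 0.967, and limma called 0 of the 10 members.

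For both HBO1 guides against ROSA26, 1 of 84 ways to split the 9 libraries into 6 and 3 gave as many called genes, namely the real one. That is the smallest share 84 splits allow, and it speaks against a chance division of these libraries. It does not exclude a difference between single cultures, since no label says that the replicates were separate ones. In that fit with 2 groups limma called 3791 genes, against at most 1 in any other split. For e11_1 against ROSA26, 1 of 10 splits, the real one, gave as many genes (2557, highest other 0), and for e12_2 against ROSA26 it was again 1 of 10 (2956, highest other 0). 10 splits are too few for a share under 0.05. For e12_2 against e11_1 the real count was 0, which all 10 splits reach by necessity, so their number says nothing about chance. The highest other split called 42 genes. It set both libraries numbered 1 against both numbered 2, with those numbered 3 on opposite sides. This points to a structure that follows the replicate number for the numbers 1 and 2. With the replicate number as a block the real count was still 0.

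For the genes called in the same direction with each guide, 2 of 100 drawn splits gave at least the real 2409. The highest other split, with 2560, kept the ROSA26 libraries as control and only traded libraries between the guides. The median of the other splits was 0. These counts speak against a chance division of ROSA26 from HBO1-guide libraries. They cannot tell whether the guides share more genes than mixed groups of their libraries would, since such a mixed split gave the higher count. For the number of lists past the camera threshold, chance cannot be excluded. In the fit with 2 groups the real split called 10 lists, 21 of 84 splits called at least as many, and the highest other split called 13. List by list, the real split gave the smallest camera p of all 84 for the Hoxa, late neutrophil, monocyte and NF-kB lists. For the other lists called, between 3 splits (stem and progenitor genes) and 32 splits (oxidative phosphorylation genes) gave a p as small, among them 5 for primary granule and for Myc and ribosome biogenesis genes, 6 for MLL fusion targets, 13 for G2 and mitosis and 16 for interferon and for stress genes.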

How the results depend on the processing

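Scaling to gene reads, scaling without Gm26924 and the mitochondrial rRNAs, and the fit without the 3 libraries numbered 1 were added after the data were seen, and the other settings were set beforehand. Kat7 stayed lower and past the threshold in every setting, with a log2 fold change of -1.12 to -1.03 when 1 library was left out. Counts of called genes moved most with a stricter threshold. At an adjusted p of 0.01, limma called 2352 genes for both guides, 1658 for e11_1 and 1877 for e12_2, and against a 1.5-fold change treat called 529, 430 and 444. Both ask for more of a gene by construction. Leaving out 1 library gave 2714 to 3455 genes for both guides, 2114 to 2773 for e11_1, 2310 to 3089 for e12_2, 1781 to 2152 shared between the guides, and 10 to 15 called lists, and e12_2 against e11_1 stayed at 0. Without the 3 libraries numbered 1 the counts were 2849, 2037 and 2358, with 1736 shared and 9 lists. Per gene reads the share of higher calls for both guides went from 52.4% to 45.04%, for e11_1 from 50.0% to 43.3% and for e12_2 from 56.0% to 47.6%, each under 10 points, and no scaling shifted the median of all genes by more than 0.1. The fit of the compared groups alone gives no value for both guides together, and called 2557 genes for e11_1 and 2956 for e12_2.

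With the estimated correlation 0 of 24 lists passed, where 12 passed at the preset one, and fry called 16. The median of the HBO1 complex list has members that go both ways, and the direction of its test turned with no filter (-0.064), with array weights (-0.055), without Kat7 (-0.051), without the 3 libraries numbered 1 (-0.0049), and without ROSA26 replicate 2 (-0.073), e11_1 replicate 1 (-0.056) or e12_2 replicate 1 (0.0049). When 1 library was left out its median ranged from -0.13 to 0.0049. Mitochondrially encoded mRNAs ranged from -0.26 without ROSA26 replicate 1 to 0.068 without ROSA26 replicate 3. With a pseudocount of 2, genes near 0 CPM in some group had smaller log2 fold changes, among them Cd177 (2.15), Ankrd22 (2.23), Parm1 (-2.13), Kynu (-1.75), Stc1 (-1.71), Mef2c (-1.22), Gbp3 (-0.93) and Cpa3 (-1.15). With DESeq2 they had larger ones, Cd177 5.63, Ankrd22 5.30, Parm1 -5.02, Kynu -4.29, Stc1 -4.28, Mef2c -2.64, Gbp3 -2.57 and Cpa3 -3.01, as did Stfa2l1 (7.55) and Igsf6 (5.10). With no filter the medians of the Hoxa (-0.78), stem and progenitor (-0.20), late neutrophil (1.35), monocyte (0.22) and NF-kB (0.36) lists were nearer 0 and still called, and that of the interferon list (-0.077) was not called. With a filter of 5 CPM the MLL fusion targets (-0.29) and late neutrophil genes (2.87) were called, and the interferon and oxidative phosphorylation lists were not. Medians also crossed 0 for mast cell markers (0.22 without the 3 libraries numbered 1), p53 targets (0.0037 with 5 CPM) and glycolysis genes (-0.0092 with no filter, -0.017 with gene reads). Without the 3 libraries numbered 1, Brd1 (limma adjusted p = 0.0534), Hat1 (0.0676), Kat6b (0.0544), Mdm2 (0.0580), Rpl7 (0.0610) and Lat (0.0757) lost the call. Brpf3 lost it with no filter (0.0767), Brd1 with no variance trend (0.0738), both with gene reads (0.0521 and 0.0629) and Kat6b with DESeq2 (0.0514), and Itga2b gained one with a replicate block (0.0400). Apart from the loss of Kat7 from its list, the cause was not tested. In total the lists kept direction and side of the threshold in 500 list-by-setting results, weakened in 35, gained a call in 31 and reversed in 8. The named genes did so in 2910, 53, 2 and 0. Genes changed less than 2-fold are those that depth and 3 libraries per group limit most.

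A replicate block, with the number in the titles as a term, called 4440 genes for both guides, 3692 for e11_1, 3931 for e12_2 and 0 between the guides, with 3180 shared and 12 lists, and kept all 3623, 2793 and 3106 calls made without it. Deviations from the group means correlated at 0.0250 to 0.482 between same-numbered libraries, with 2 of 9 such pairs at or under 0.1. The median was 0.256, against -0.201 between libraries of different groups and numbers. The numbers were not used as pairing in the main fit. All 9 libraries correlated best with a library of their own number, a hint from the data and not from the design.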

Other observations

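The genes in the next paragraphs were chosen after their values were seen, and so were the tests on neutrophil genes, on the Abcb1a region, on the Hoxa genes and on the neighbours of Kat7, whereas the test of neighbouring genes was set before its result was known.

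Cebpd, a transcription factor gene, rose from 3.76 CPM with ROSA26 to 18.9 and 23.2 CPM with e11_1 and e12_2 (log2 fold change 2.33, limma adjusted p = 1.2e-08), and Spi1, which encodes PU.1, from 25.1 to 54.1 and 48.9 CPM (1.02, limma adjusted p = 5.2e-06), while Cebpa differed by 0.15 (limma adjusted p = 0.311), or by 0.29 without ROSA26 replicate 1 and -0.033 without ROSA26 replicate 3. Irf8 fell by 0.97, without a call when ROSA26 replicate 1 (limma adjusted p = 0.0830) or 3 (0.0553) was left out. Mxd1, a Myc antagonist (2.35), and the cell cycle inhibitor gene Cdkn1b (1.03) rose. Lta4h rose from 36.1 to 193 and 249 CPM (2.74) and the leukotriene receptor gene Ltb4r1 by 2.64, as did complement C3 (2.99), the antioxidant genes Gsr (2.00) and Prdx5 (2.16), and the iron exporter gene Slc40a1 (3.52). Ncf4 (0.78) and Cyba (0.85), which encode subunits of the phagocyte oxidase, rose less than Ncf1 (3.71).

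Among other genes, Runx1t1 went from 43.5 to 9.33 and 9.60 CPM (-2.18, limma adjusted p = 2.2e-06), Tox from 18.5 to 4.24 and 4.90 CPM (-1.91), and Zbtb16 from 18.9 to 5.55 and 6.14 CPM (-1.66). The RNA-binding protein gene Msi2 (-1.48) and Hmga2 (-0.92) fell as well. Brd2 and Brd3, which encode targets of I-BET, did not pass the test: Brd2 differed by 0.11 (limma adjusted p = 0.289) and Brd3 by -0.01 (limma adjusted p = 0.960).

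The rise of late neutrophil genes was set against technical causes. Its median of 2.04 came down to no less than 1.99 under the other scalings and to no less than 1.96 when 1 library was left out, the lowest being without ROSA26 replicate 2. If leukaemic cells had given way to other blood cells of every type, the markers of those types would rise alike. Instead, 12 measured mast cell, T and NK, dendritic, erythroid and megakaryocyte markers had a median of -0.41, with 1 higher and 5 lower. The difference of medians was 2.45 (SE 0.676). That SE is across genes, which are not independent replicates, and leaves out the spread between libraries. Monocyte and macrophage genes were not among the 12, and of 11 measured, 8 rose and 2 fell (median 0.92). The 12 markers cannot exclude a larger share of neutrophils alone, or of neutrophils and monocytes, since no marker here tells leukaemic cells of these types from others. These values are consistent with the hypothesis that cells given HBO1 guides may mature towards neutrophils. Not all genes moved as that hypothesis alone would have it. The late neutrophil genes Ltf (0.84, limma adjusted p = 0.345) and Cxcr2 (0.62, limma adjusted p = 0.0872) did not pass. Cxcr2 passed without ROSA26 replicate 1 (limma adjusted p = 0.00819). Of 24 G2 and mitosis genes, which are active in dividing cells, 13 rose and 0 fell. Whether many cells shift a little or a few shift far was not tested, since bulk RNA holds no value for single cells.

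Abcb1a fell together with its neighbours Rundc3b, Abcb1b and Abcb4 on chromosome 5, by 23.6-fold, 4.81-fold, 8.56-fold and 12.7-fold from mean CPM without a pseudocount. The flanking genes did not pass the test with all libraries, Slc25a40 at -0.58 (limma adjusted p = 0.108, but 0.0452 without e11_1 replicate 1) and Crot at 0.00 (limma adjusted p = 0.991). Loss of the chromosome segment as the only cause would lower the genes by 1 common factor, and the largest and smallest log2 ratios differed by 2.30 (SE 0.496), but Rundc3b, at 0.519 and 0.611 CPM with the HBO1 guides, lies too near 0 for this to exclude the loss. Reads shared with Abcb1a stay open for the fall of Abcb1b, which was smaller by 1.47 (SE 0.390), as it would be with some reads of its own. Regulation of the region and growth of cells that differed there from the start were not tested.

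Hoxa genes fell by log2 ratios of mean CPM that differed by 2.09 (SE 0.262) between Hoxa10 and Hoxa7, which overlaps a tested transcript and is uncertain, and by 1.14 (SE 0.109) between Hoxa10 and Hoxa9, which do not, against the single factor that loss of the segment would give. Reads of overlapping transcripts could not account for the fall alone, since Hoxa9 and Hoxa10, which overlap no tested gene, had a median log2 fold change of -2.25 and 2 of 2 were called lower. Without any 1 library the median of the 5 genes stayed at -1.55 or lower. That the HBO1 guides lower the cluster as a target of the MLL fusion is a hypothesis consistent with these values, and whether the cells had first matured for another reason was not tested.

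The nearest tested genes beside Kat7 did not fall with it: Tac4 rose by 1.94 and Fam117a by 0.89. Across the genome, neighbouring genes changed together to a small degree. The log2 fold changes of 8622 pairs of consecutive tested genes correlated at 0.110, above the upper limit of 0.0214 from shuffled orders (permutation p = 0.0001, the smallest that 10000 shuffles can give). For e12_2 against e11_1 the correlation was 0.00516 (permutation p = 0.640). Overlapping genes, and genes whose symbols begin with the same letters, were not counted as pairs. Regulation in neighbourhoods may add to this value, as may related genes with unlike symbols, which were not set apart.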
